A study of Mus musculus with 8 samples.

How the data were processed

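RNA was measured in neurospheres, floating clusters of neural stem and progenitor cells grown from the hippocampi of C57Bl6/J mice at postnatal day 0 or 1. Per the labels' protocols, spheres at passage 2 were dissociated and the cells were kept for 48 h with either FK866 at 10 nM or its solvent DMSO, diluted 1 in 1000. FK866 inhibits nicotinamide phosphoribosyltransferase (Nampt). The labels give 4 samples for each treatment and 2 litters, with replicates 1 and 2 in litter 1 and replicates 3 and 4 in litter 2. A code in the labels is shared by the DMSO and the FK866 sample of the same replicate number, and such a pair is called a culture here. The labels do not say whether a code stands for an animal. The p-values therefore measure the spread between 4 cultures from 2 litters.

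Per the labels' protocols, 200 ng of total RNA per sample was amplified with T7 polymerase and labelled with biotin, 1 colour per array. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. The deposited table without background subtraction or normalization holds the mean bead intensity of 25697 probes on each array, with the number of beads, per the file headers. A detection p-value for each probe on each array stands beside it, per the file headers. The authors also deposited each intensity after background subtraction, which removed 1 constant per array, and after average, quantile and cubic spline normalization of the subtracted values. A further table by the authors holds a Z score for 18138 gene symbols on each array. For the 18116 symbols compared, that score equalled the Z score per array of the mean log10 intensity floored at 1, within 4.97e-08. No column of per-sample values was left unassigned to a sample. The files give no slide or scan date, so the litter was the only batch that could be examined.

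The intensities without background subtraction were the starting point. They were corrected with the normal-exponential method of limma's neqc function, which took the background from the detection p-values, then quantile normalized with an offset of 16 and taken to log2 (limma 3.58.1 in R 4.3.3). Probes with a detection p under 0.05 on at least 4 of the 8 arrays were kept, which left 11797 probes. Gene symbols were updated through the RefSeq annotation of GRCm38.p6. By Entrez identifier 23788 probes were named, another 423 took the name of a matched probe with the same symbol, and 1486 kept the symbol of the array's own annotation. The probe with the highest mean over all arrays stood for each gene, which gave 8919 genes. Of these, 2124 had several tested probes, and in 30 genes the probes were called in opposite directions. Probe coordinates are those of the array's annotation, whose genome build is not given in the sources used here. Probes cannot reliably tell apart near-identical copies such as histone genes, Lyz1 and Lyz2, or ribosomal protein genes and their pseudogenes, so values of these genes are uncertain.

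FK866 was compared with DMSO by limma's moderated test (lmFit and eBayes, two-sided) on all 8 arrays, without a block, and p-values were adjusted by the Benjamini-Hochberg method. Genes with an adjusted p under 0.05 were called. A gene detected on no array of a group has only a bound there. Its fold is written as "at least", the detected group's mean set against, per array, the higher of the dim probe's own value and the lowest value among the detected probes. Gene lists were compared with all other tested genes by camera with a preset correlation of 0.01 between genes, for lists with at least 5 measured members. The same test was run with the correlation estimated per list, and fry was run as another set test. A litter term and an interaction of litter with treatment were tested in separate limma fits.

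The 41 lists, the tests, the rule for naming genes and the alternatives were chosen before the data were examined, except that the fits without culture 4 in both groups, the test of list medians over other splits of the arrays, the litter fits with the culture as a random block (duplicateCorrelation) or as the unit, and the tests named as such in the closing observations were added afterwards. The lists cover NAD metabolism, the cell cycle, stress and metabolic pathways, and markers of the cell types a hippocampal culture can hold. Genes named in the text are Nampt with the measured genes of NAD synthesis, and the 10 largest rises and 10 largest falls among called genes that moved the same way in all 4 cultures, without gene models that carry only a clone-type symbol. For each list described by gene, they are also the 3 called members with the smallest p, and for a list of another cell type the brightest member. Genes named outside this rule were chosen after their values were seen, as is said beside them. A few genes that the rule names are not reported here. The choice of 28 lists to describe by gene was made after the results were seen, and the remaining 13 are given as counts.

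Replicate numbers were checked for pairing. Across genes, the deviations from the group means of the DMSO and FK866 samples with the same number correlated with r of 0.16, 0.33, 0.21 and 0.37 for cultures 1 to 4. Each was above the highest correlation of that DMSO sample with another number, and genes are not independent replicates. The codes in the labels give the same pairing, so the replicate block was run as an alternative.

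Alternatives covered the background correction, the normalization (including the authors' own normalized tables), the detection filter, the variance model, array weights, the rule for several probes, litter and replicate blocks, each litter alone, thresholds, the set test, and leaving out each sample. The number of arrays limits the precision. On simulated data for this comparison, with 8919 genes of which 200 were changed and errors drawn independently between genes, 71.6% of genes changed 1.5-fold, 97.1% of those changed 2-fold and 99.7% of those changed 4-fold were recovered. On average over 10 runs, 4.87% of calls were false. With no change simulated, 0.2 genes and 0.1 lists were called on average. The simulation does not cover genes that vary together. It also does not cover a share of changed genes as large as the 49.8% called here, on which the cutoff of the adjusted p depends.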

Results

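Gene expression was measured on 8 bead arrays of mouse hippocampal neurospheres, 4 treated for 48 h with FK866 and 4 with DMSO. Nampt makes nicotinamide mononucleotide, from which mammalian cells rebuild NAD, and the study asked what this enzyme does in hippocampal stem and progenitor cells. On each array 44.0% to 46.2% of the 25697 probes were detected, at a median intensity of 191 to 206 and with a median of 39 beads per probe. Samples of the same group correlated with r of 0.981 to 0.994 across the tested genes, which are not independent replicates. The lowest of these correlations involved culture 4. The first principal component held 71.1% of the variance and separated FK866 from DMSO. The second held 12.2% and set culture 4 apart from the other cultures in both groups.

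**Figure D1:**
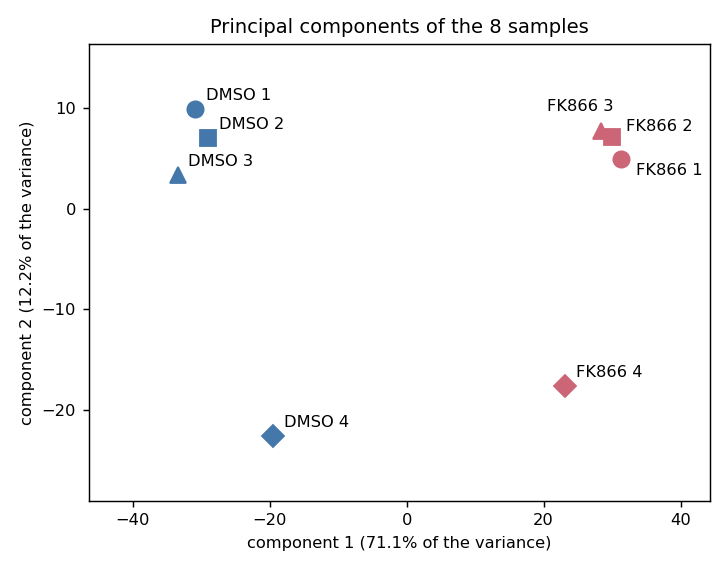
Scores of the 8 samples on the first and second principal components of log2 normalised intensity, labelled by treatment and culture. Component 1 (71.1% of the variance) separates DMSO on the left from FK866 on the right, and component 2 (12.2%) separates culture 4 of both groups.

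The comparison of FK866 with DMSO asked which genes respond when Nampt is inhibited. Genes of DNA replication, DNA repair, the cell cycle, ribosome production and nucleotide synthesis fell, and genes of the lysosome, of antioxidant defence and of growth arrest rose. These calls of gene lists were made with a preset correlation; none held with an estimated correlation (adjusted p of at least 0.36), and their number does not exclude chance. Of 8919 genes tested, 4442 (49.8%) changed, 2208 of them higher and 2234 lower in FK866. At least 2-fold changes numbered 418 higher and 390 lower, and 4294 of the changed genes moved the same way in all 4 cultures. The median over all genes was 0.01 on the log2 scale. Detection on no DMSO array was found for 99 of the changed genes and on no FK866 array for 60. Within litter 1, with 2 samples per group, 1981 genes were higher and 1975 lower, and within litter 2 these numbers were 552 and 536. With litter as a block 2243 were higher and 2232 lower, and without culture 4 in both groups, a fit chosen after the data were seen, 2420 were higher and 2375 lower.

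The largest rise measured on detected probes was that of Ppfibp2, a member of the liprin family of scaffold proteins. Its log2 intensity went from 7.34 ± 0.54 in DMSO to 11.5 ± 0.14 in FK866 (SD, n = 4 each), an 18.0-fold rise (adjusted p = 3.1e-06). Osgin1, an oxidative stress response gene, was at least 4.96-fold higher (adjusted p = 1.7e-06). The increase of Cox8b, which encodes a subunit of cytochrome c oxidase, was 3.28 ± 0.23 on the log2 scale (± SE, as for all log2 changes below). Rragd, a Rag GTPase of the mTORC1 pathway at the lysosome, rose by 3.20 ± 0.26, and Fbxo32, a ubiquitin ligase subunit known from muscle atrophy, by 3.19 ± 0.24. Others were Trim36, a ubiquitin ligase (at least 7.06-fold higher), and St8sia2, which adds polysialic acid to the neural cell adhesion molecule (at least 4.77-fold). Fabp3, a fatty acid binding protein, was at least 4.87-fold higher, Rnase1 at least 4.18-fold higher, and Nuak1, a kinase related to AMPK, rose by 2.92 ± 0.20. The adjusted p-values of these 10 genes lay between 6.6e-08 for Trim36 and 1.9e-05 for Rragd. The sizes of changes in dim genes, the bounds included, hold for background-corrected values: without that correction, which leaves the background in both groups and so makes ratios smaller, the log2 changes of 36 of the 94 called genes under the naming rule shrank by over 1.5 times, to 1.59 for Trim36 and 1.48 for St8sia2, and all 94 were still called.

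Among the largest falls was that of Ccne2, the gene of cyclin E2, which drives entry into S phase. It was detected on all 4 DMSO arrays and on no FK866 array, and was at least 5.37-fold lower (adjusted p = 6.1e-06). Tk1, the thymidine kinase of cycling cells, fell by 2.65 ± 0.23 on the log2 scale, a 6.28-fold decrease (adjusted p = 2.6e-05). The histone H2A genes H2ac21 (-2.66 ± 0.21) and H2ac11 (-2.32 ± 0.16) fell too. Others were Fam111a (-2.43 ± 0.14), Cep41, which encodes a centrosomal protein (-2.42 ± 0.10), Ung, the uracil-DNA glycosylase (-2.41 ± 0.19), and Gna14, a G protein subunit (-2.26 ± 0.29). Egr4, an immediate early transcription factor, was at least 2.59-fold lower. Pdgfra, the growth factor receptor of oligodendrocyte progenitors, fell by 2.19 ± 0.25 on the log2 scale (adjusted p = 0.00010) and was detected on 4 DMSO arrays and 1 FK866 array, with a range of -2.97 to -0.99 over the alternatives. Gna14 had the highest adjusted p of the 10, 0.00017.

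**Figure D2:**
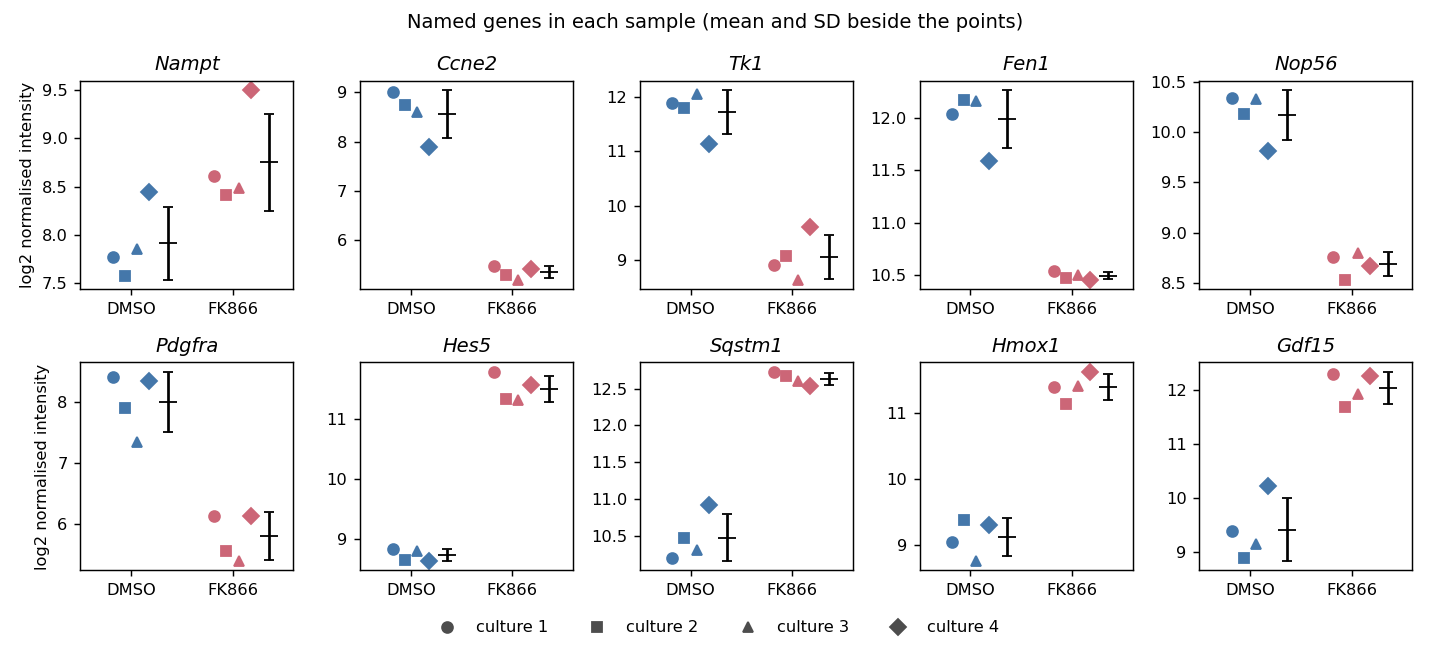
Log2 normalised intensity of 10 genes in each sample, with 1 symbol per culture, and the mean and SD (n = 4) of each group beside the points; each panel has its own axis, which does not start at 0. Ccne2, Tk1, Fen1, Nop56 and Pdgfra are lower in all 4 FK866 samples than in any DMSO sample, and Hes5, Sqstm1, Hmox1 and Gdf15 are higher, while the highest DMSO value of Nampt lies within the range of its FK866 values.

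Nampt itself, the target of the inhibitor, rose 1.79-fold, from 7.91 ± 0.37 to 8.75 ± 0.50 log2 intensity (SD, n = 4 each; adjusted p = 0.020). The tested probe lies on chromosome 12 from 33531624 to 33531673. Another Nampt probe, from 33524059 to 33524108, was detected on 3 arrays, too few to be tested, so the rise rests on 1 probe. Slc12a8, reported as a carrier of nicotinamide mononucleotide, was detected on no DMSO array and all 4 FK866 arrays and was at least 1.36-fold higher (adjusted p = 0.00023). Nadk, which turns NAD into NADP, fell by 0.28 ± 0.09 on the log2 scale (adjusted p = 0.026). Afmid of the kynurenine pathway (-0.34 ± 0.13, adjusted p = 0.059), Nmnat2 (0.27 ± 0.21, adjusted p = 0.31) and Naprt of the nicotinic acid route (-0.10 ± 0.17, adjusted p = 0.67) did not pass. Of the 6 measured genes of NAD synthesis, 2 thus rose and 1 fell (2 and 2 adjusted over the list alone). The list was not shifted against other genes (camera adjusted p = 0.78), though fry called it (adjusted p = 0.045). Among 10 genes of NAD-consuming enzymes 4 rose and 2 fell, with no shift of the list (adjusted p = 0.97). The poly(ADP-ribose) polymerase genes Parp2 (-1.07 ± 0.10) and Parp1 (-0.85 ± 0.10) fell, and Tnks, the gene of tankyrase, rose by 0.78 ± 0.14. The calls of Nampt and Nadk were fragile: that of Nampt was lost without DMSO replicate 1 (adjusted p = 0.0501), without DMSO replicate 2 (0.0571), within litter 2 (0.175) and in the authors' Z scores (0.0717), with a range of 0.00036 to 0.175 over its alternatives. Its log2 change in these log2 fits, 0.79, 0.73 and 0.84, was close to the 0.84 with all samples, and with the replicate block its adjusted p was 0.00036. That of Nadk was lost without DMSO replicate 1 (0.0799) or 3 (0.0734), without FK866 replicate 2 (0.0629) or 3 (0.0557), in each litter alone and in the Z scores, with a range of 0.0081 to 0.41.

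Of the 41 gene lists, 39 had enough measured members to be tested, and camera called 15, with 8 higher and 7 lower in FK866. The median of each of the 15 had the same sign in both litters, and all 15 were also called with litter or replicate as a block and without culture 4. None was called with an estimated correlation, for which the smallest adjusted p was 0.36 with all samples and 0.0574 without culture 4. Of the 35 ways of splitting the 8 arrays into 4 and 4, 6 called at least 15 lists, the real split included, so the number of lists does not exclude chance. In a test added after the results were seen, no other split gave a median as far from 0 in 14 of the 15, all but the astrocyte markers, with an exact permutation p of 0.0286, the smallest that 35 splits allow (0.0531 after Benjamini-Hochberg adjustment over the 39 lists). The same held for 21 of all 39 lists, 7 of them not called by camera, so this does not set the called lists apart. Where no separate count is given below, the count adjusted over the list alone was the same as that over all genes tested.

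**Figure D3:**
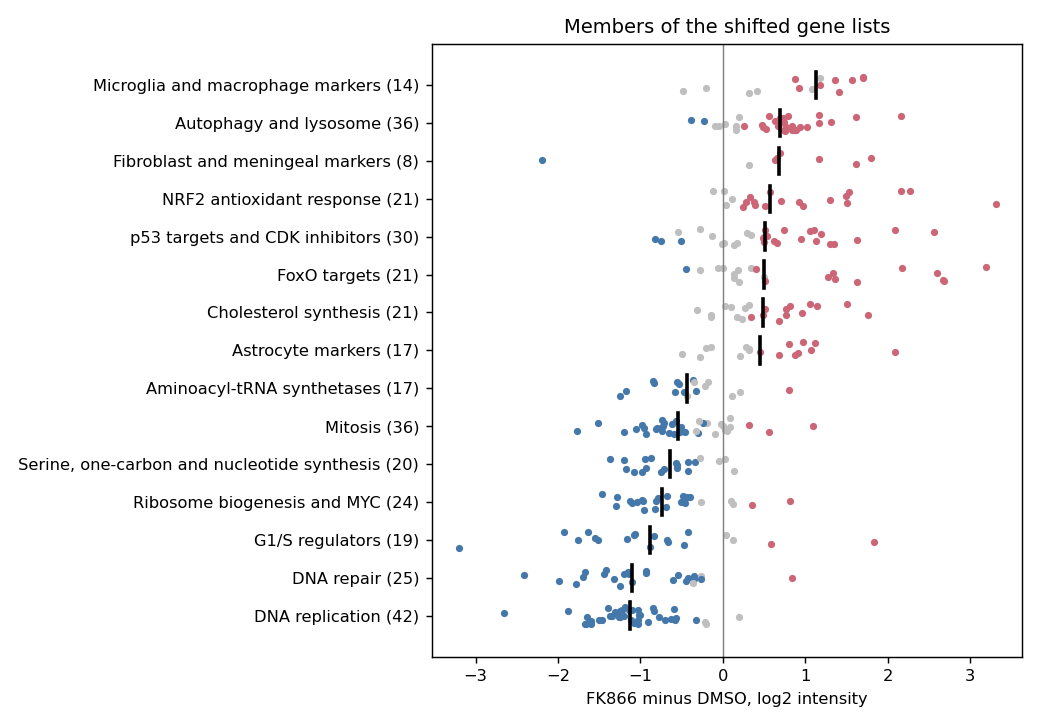
Log2 change (FK866 minus DMSO) of each measured member of the 15 lists called by camera, with the number of members in parentheses; red and blue points passed the test and grey ones did not, and the black bar is the list's median. The medians run from -1.13 for DNA replication to 1.13 for microglia and macrophage markers.

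Genes of DNA replication fell almost without exception. Of 42 measured members 39 fell and 0 rose, with a median of -1.13 on the log2 scale (adjusted p = 7.9e-15, and adjusted p = 0.36 with an estimated correlation). They included Tk1, Fen1, the flap endonuclease (-1.50 ± 0.13), Pold1, the catalytic subunit of DNA polymerase delta (-1.40 ± 0.12), and Rpa3 of the single-strand binding complex (-1.35 ± 0.09). DNA repair genes moved with them: 22 of 25 fell (23 adjusted over the list alone) and 1 rose, with a median of -1.11, or -0.94 with genes at their bound (adjusted p = 2.5e-08, and adjusted p = 0.36 with an estimated correlation). Beside Ung, the checkpoint gene Clspn fell by 1.70 ± 0.12 and the recombination gene Rad54b by 1.42 ± 0.10. Among 19 regulators of the G1/S transition 15 fell and 2 rose, with a median of -0.88 (adjusted p = 4.2e-05, and adjusted p = 0.36 with an estimated correlation). Skp2, a ubiquitin ligase subunit that removes a cyclin-dependent kinase inhibitor, fell by 1.52 ± 0.10, whereas E2f3, a transcription factor of S phase genes, rose by 1.83 ± 0.10. Of 36 genes of mitosis 23 fell (24 adjusted over the list alone) and 3 rose, with a median of -0.54, or -0.51 with genes at their bound (adjusted p = 0.00013, and adjusted p = 0.54 with an estimated correlation). The kinetochore gene Cenpk fell by 1.77 ± 0.13 and Birc5, the gene of survivin, by 1.20 ± 0.12. Pttg1, the gene of securin, was at least 1.27-fold higher. By culture, the median of the replication list was -1.25, -1.35, -1.36 and -0.65 for cultures 1 to 4. The smaller change in culture 4 came more from its DMSO sample. Against the mean of the other cultures of the same group, the list's median was -0.52 in DMSO replicate 4 and 0.15 in FK866 replicate 4.

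Genes that supply growth fell as well. Of 24 genes of ribosome biogenesis and MYC 19 fell and 2 rose, with a median of -0.74, or -0.71 with genes at their bound (adjusted p = 3.4e-05, and adjusted p = 0.36 with an estimated correlation). Nop56 and Gar1, which encode proteins of small nucleolar particles, fell by 1.47 ± 0.13 and 1.29 ± 0.11, and Ncl, the gene of nucleolin, by 1.30 ± 0.12. Among 20 genes of serine, one-carbon and nucleotide synthesis 16 fell and 0 rose, with a median of -0.65 (adjusted p = 7.7e-06, and adjusted p = 0.36 with an estimated correlation). Umps, which completes UMP synthesis, fell by 1.20 ± 0.13, Shmt2, the mitochondrial serine hydroxymethyltransferase, by 1.17 ± 0.13, and Ctps, the gene of CTP synthase, by 0.93 ± 0.09. Of 17 aminoacyl-tRNA synthetase genes 10 fell (13 adjusted over the list alone) and 1 rose, with a median of -0.44 (adjusted p = 0.0028, and adjusted p = 0.36 with an estimated correlation). Vars fell by 1.25 ± 0.12, Lars by 1.17 ± 0.11 and Wars by 0.84 ± 0.10. Cytosolic ribosomal protein genes were by contrast mostly not called, with 1 of 48 higher and 5 lower (0 and 3 adjusted over the list alone; list adjusted p = 0.65).

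Lysosomal and autophagy genes rose together. Of 36 measured members 28 rose and 2 fell, with a median of 0.69 (adjusted p = 5.3e-08, and adjusted p = 0.36 with an estimated correlation). Sqstm1, the autophagy receptor p62, rose by 2.16 ± 0.15, a 4.47-fold increase. The lysosomal sialidase gene Neu1 rose by 1.61 ± 0.14. Markers of microglia and macrophages, which are rich in lysosomes, moved the same way, with a median of 1.13. Among 21 genes of the NRF2 antioxidant response 17 rose and 0 fell, with a median of 0.57 (adjusted p = 7.7e-06, and adjusted p = 0.36 with an estimated correlation). They included Osgin1, Sqstm1 and Hmox1, the inducible heme oxygenase, which rose by 2.27 ± 0.15.

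Genes of growth arrest rose. Of 30 p53 targets and cyclin-dependent kinase inhibitors 18 rose and 3 fell, with a median of 0.51 (adjusted p = 0.00071, and adjusted p = 0.36 with an estimated correlation). All 3 Gadd45 genes, which are induced by growth arrest and DNA damage, were among the rises, Gadd45b by 2.55 ± 0.17, Gadd45a by 1.63 ± 0.10 and Gadd45g by 1.06 ± 0.10. Gadd45b was detected on 1 DMSO array, and its change ranged from 1.22 to 3.39 over the alternatives. Of 21 FoxO targets 11 rose (12 adjusted over the list alone) and 1 fell, with a median of 0.49 (adjusted p = 0.00025, and adjusted p = 0.43 with an estimated correlation). Beside Fbxo32, Sesn3, a sestrin gene, rose by 2.18 ± 0.12. The integrated stress response did not move as a group: of 32 targets of ATF4 and related genes 9 rose and 12 fell (13 adjusted over the list alone), with an adjusted p of 0.997 for the list. Its median was -0.0031 and its mean 0.13, and camera's direction was upward. Within it, Gdf15, a stress-induced secreted factor, rose by 2.62 ± 0.26, Atf3 by 1.79 ± 0.15 (detected on 2 DMSO arrays, with a range of 0.84 to 2.16 over the alternatives) and Sqstm1 as given above. Of 16 immediate early and growth factor feedback genes 3 rose and 5 fell (list adjusted p = 0.27). Spry4 and Dusp6, feedback inhibitors of growth factor signalling, fell by 1.49 ± 0.10 and 0.85 ± 0.09, and Zfp36, an mRNA decay factor, rose by 0.61 ± 0.10.

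Among metabolic genes, those of cholesterol synthesis rose. Of 21 members 12 rose and 0 fell, with a median of 0.49 (adjusted p = 0.0026, and adjusted p = 0.72 with an estimated correlation). Lss, the lanosterol synthase gene, rose by 1.76 ± 0.22 and Srebf2, the transcription factor of the pathway, by 0.77 ± 0.09. Oxidative phosphorylation was not shifted (adjusted p = 0.33), with 12 of 60 genes higher and 5 lower (8 and 2 adjusted over the list alone). Its called genes included Ndufa1 of complex I (0.51 ± 0.09) and Cox6c and Cox6b1 of cytochrome c oxidase (0.50 ± 0.09 and 0.37 ± 0.08). Neither glycolysis (2 of 18 rose and 2 fell, adjusted p = 0.82) nor the hypoxia response (1 of 19 rose and 1 fell, adjusted p = 0.70) was shifted with all samples. With the replicate block 3 glycolysis genes rose and 5 fell, and 3 hypoxia genes rose and 8 fell (hypoxia list adjusted p = 0.20). Eno2 and Aldoc of glycolysis rose by 1.44 ± 0.22 and 0.80 ± 0.11, and Hif1a, the oxygen-regulated transcription factor, by 0.71 ± 0.13. Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell by 1.86 ± 0.52 (adjusted p = 0.014), a call that was lost with a trended, robust variance model (adjusted p = 0.0515) and within litter 2 (0.0932), over a range of 7.9e-05 to 0.0932. The hypoxia result also depended on culture 4, in which most of these genes were high under both treatments: without that culture 10 of 19 fell and 3 rose (list adjusted p = 0.095, median -0.46), and without FK866 replicate 4 alone the list was called (adjusted p = 0.0426, over a range of 0.0426 to 1.00). With an estimated correlation its adjusted p was 0.97 with all samples, 0.68 without culture 4 and, in a fit added after the data were seen, 0.82 without FK866 replicate 4. Without DMSO replicate 4 its adjusted p was 0.834 and its median -0.10, while camera's direction was upward.

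Of 15 measured markers of the oligodendrocyte lineage and its progenitors 7 fell and 1 rose. The list was not called by camera (adjusted p = 0.18) but was called by fry (adjusted p = 0.00022). Beside Pdgfra, the lineage transcription factor genes Nkx2-2 and Olig2 fell by 1.33 ± 0.10 and 0.96 ± 0.11. Of 21 markers of neural stem cells and radial glia 9 rose (11 adjusted over the list alone) and 5 fell (list adjusted p = 0.13). Hes5, a Notch effector of neural progenitors, rose by 2.77 ± 0.12, a 6.80-fold increase (adjusted p = 1.2e-06), Id2 by 1.04 ± 0.11 and Msi2 by 0.94 ± 0.12. Of 13 Notch pathway genes 8 rose and 2 fell (list adjusted p = 0.13), among them the ligand gene Jag1, which rose by 1.59 ± 0.24, and the receptor-modifying Lfng, which fell by 1.53 ± 0.16 (detected on 2 FK866 arrays, with a range of -1.92 to -0.65). Astrocyte markers rose as a list, with 9 of 17 higher and 0 lower and a median of 0.45 (adjusted p = 0.011, and adjusted p = 0.56 with an estimated correlation). Apoe rose by 2.08 ± 0.25, Cst3 by 1.06 ± 0.09 and Sparcl1 by 0.87 ± 0.11, whereas Slc1a3, the brightest marker, was at -0.15 ± 0.10 (adjusted p = 0.25). Neuron and neuroblast markers went both ways, with 6 of 15 higher and 4 lower (list adjusted p = 0.70), a median of -0.04 and a mean of 0.09. Elavl3 and Prox1 rose by 0.96 ± 0.09 and 0.95 ± 0.12 (Prox1 was not called in the authors' Z scores), and Elavl4 fell by 0.95 ± 0.12. Map2, the brightest, was lower by 0.28 on its brightest probe (-0.28 ± 0.08, adjusted p = 0.019), but its probes disagreed (-0.28 to 0.41) and the call was lost in each litter, without DMSO replicate 2 (0.0602) and without DMSO replicate 3 (0.0514), over a range of 0.0049 to 0.25.

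Markers of non-neural cells were mostly higher in FK866. Of 14 microglia and macrophage markers 8 rose and 0 fell, with a median of 1.13, or 1.00 with genes at their bound (adjusted p = 0.018, and adjusted p = 0.76 with an estimated correlation). Cd68 was at least 2.19-fold and Trem2 at least 1.77-fold higher, each detected on no DMSO array. Lyz1, the brightest, was at 1.08 ± 0.54 (adjusted p = 0.12), and was called with litter or replicate as a block (0.00090 and 0.00049), over a range of 0.00049 to 0.30. Of 20 listed fibroblast and meningeal markers only 8 were measured. The collagen genes Col1a1, Col1a2 and Col3a1, chosen after the results were seen, were detected on no array. The list therefore does not show that fibroblasts were present. Its measured markers rose as a list, with 6 of 8 higher (7 adjusted over the list alone) and 1 lower, Pdgfra. Their median was 0.67 (adjusted p = 0.034, and adjusted p = 0.36 with an estimated correlation). Thbs2 was at least 1.97-fold higher, Fbln1 rose by 0.69 ± 0.13 and Igf2 by 0.66 ± 0.11. Of 6 ependymal and choroid plexus markers 3 rose and 1 fell (list adjusted p = 0.70). Ttr and S100a11 rose by 1.35 ± 0.22 and 0.76 ± 0.08, and Dynlrb2, a dynein gene of ciliated cells, fell by 1.64 ± 0.24. Only 4 endothelial and mural markers were measured, too few for a list test: Rgs5 rose by 1.18 ± 0.22 (range 0.54 to 1.47 over the alternatives), Acta2 rose by 0.80 ± 0.13 on its brightest probe while its other probe was at -0.16, Flt1 fell by 1.10 ± 0.23 (range -1.35 to -0.46), and Cspg4 was at 0.36 ± 0.21 (adjusted p = 0.18). Cspg4 was called with the replicate block (0.0177) and without DMSO replicate 4 (0.0442), over a range of 0.0177 to 0.42. None of the erythroid markers was measured. The microglial list lost its call without DMSO replicate 4 (adjusted p = 0.0546) and with fry (0.0521), over a range of 1.8e-05 to 0.76, and the fibroblast list without a detection filter (0.100) and in the Z scores (0.0513), over a range of 0.00035 to 0.36.

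**Figure D4:**
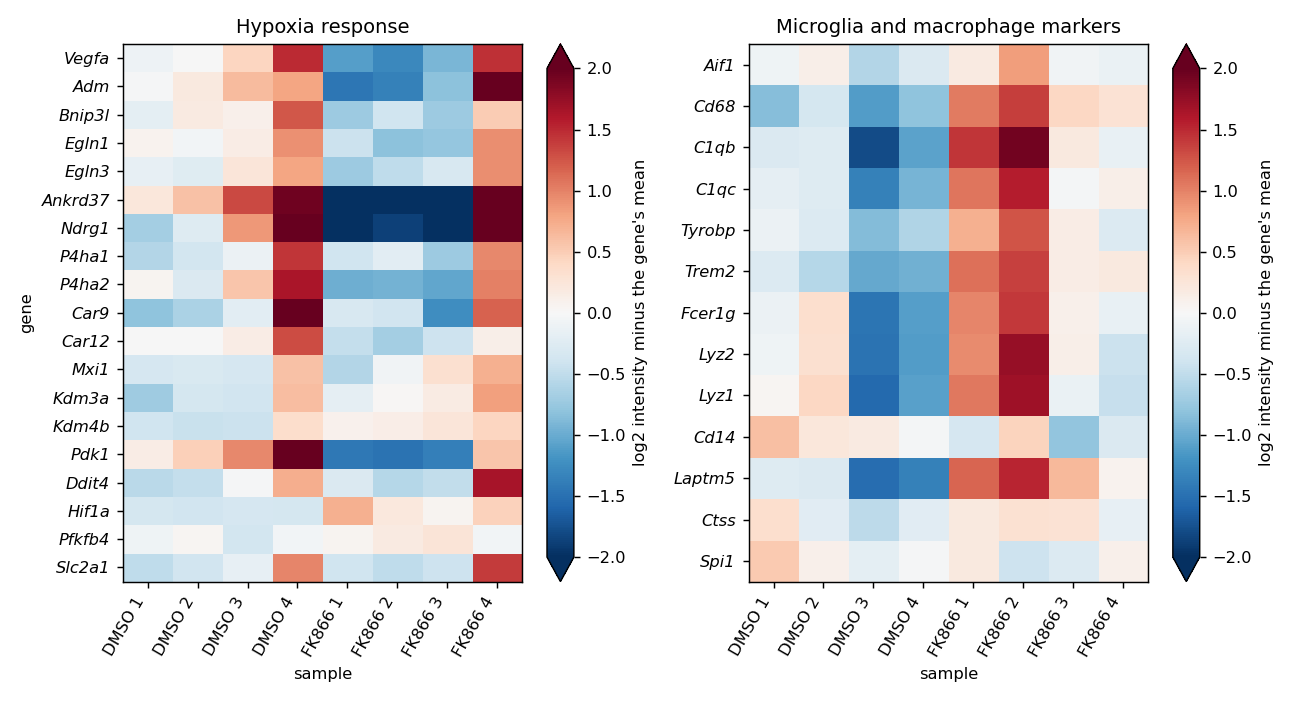
Log2 normalised intensity of each gene minus its mean over the 8 samples, for the 19 measured genes of the hypoxia response (left) and 13 of the 14 microglia and macrophage markers (right); colours are limited to -2 to 2. Most hypoxia genes are highest in culture 4 of both groups, and most microglial markers are higher in FK866 than in DMSO and lower in cultures 3 and 4 than in cultures 1 and 2.

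By camera, the remaining lists were not shifted against the other tested genes, and the adjusted p-values here are those of camera. Fry called some of them, as given below. Of 16 genes of the unfolded protein response of the endoplasmic reticulum 4 rose and 6 fell (adjusted p = 0.46). The mitochondrial ribosome had 7 of 55 genes higher and 18 lower (adjusted p = 0.11), and mitochondrial biogenesis 4 of 17 higher and 9 lower (adjusted p = 0.16). In the tricarboxylic acid cycle 6 of 20 genes rose and 4 fell (adjusted p = 0.90), and in fatty acid synthesis 4 of 15 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.42). The proteasome had 2 of 29 genes higher and 1 lower (1 and 0 adjusted over the list alone; adjusted p = 0.21), and the heat shock proteins 4 of 16 higher and 4 lower (adjusted p = 0.64). Among interferon response genes 5 of 15 rose (6 adjusted over the list alone) and 3 fell (adjusted p = 0.18), and 10 rose and 3 fell with the replicate block. Apoptosis regulators had 6 of 20 members higher and 6 lower (7 and 7 adjusted over the list alone; adjusted p = 0.95). Of 9 myelin genes 2 rose and 1 fell (adjusted p = 0.70), or 3 and 2 with the replicate block, and of 14 targets of Wnt and Hedgehog signalling 2 rose and 3 fell (2 and 2 adjusted over the list alone; adjusted p = 0.72).

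The litters were compared because the labels give them as the batch. With each array as a sample, litter 2 was lower than litter 1 in 14 genes and higher in 0, and 6 of the 14 belong to the list of microglia and macrophage markers. Each litter holds only 2 cultures, and in fits added after the data were seen limma called 11 genes with the culture as a random block and 0 with the mean of each culture's arrays (520 and 413 at an unadjusted p under 0.05). The litter values below therefore describe these arrays. Lyz1 and Lyz2, the lysozyme genes, were lower by 1.61 and 1.45 on the log2 scale (-1.61 and -1.45, adjusted p = 0.018 and 0.032). The complement genes C1qb (-1.40) and C1qc (-1.10), the chemokine genes Ccl3 (-1.66), Ccl4 (-1.65) and Ccl9 (-1.28), and Fcer1g (-1.31), Cd52 (-1.43) and Laptm5 (-1.08) were in the same set, as were Cd99l2, Cyp4f14, Ifi27 and Lgals3bp. Except for Lyz1 these genes lie outside the naming rule and were named after their values were seen. At an unadjusted p under 0.05 the litter term gave 608 genes. The response to FK866 was not found to differ between litters: the interaction gave 0 genes in limma (200 at an unadjusted p under 0.05), and 1 gene without FK866 replicate 3. Across genes, which are not independent replicates, the changes in litter 1 and litter 2 correlated with r = 0.917. Leaving out single samples reduced the litter genes to 1 without DMSO replicate 2 or FK866 replicate 2, to 2 without DMSO replicate 3 or FK866 replicate 4, and to 3 without DMSO replicate 1 or FK866 replicate 3. Under other processing choices with each array as a sample their number ranged from 2 to 31.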

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

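The tests of array quality and of a litter difference below were chosen after the result was seen. Within each group of 4, a sample was singled out where its gap to the nearest other sample, divided by the group's range, exceeded Dixon's critical value for 4 samples. This was so in 18 of 204 groups (102 values in each treatment), where chance alone gives about 1 in 20, or 10.2. Of the 18, 12 were in culture 4.

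In DMSO replicate 4, log2 intensity was lowest for Dynlrb2 (7.23, others 8.18 to 8.31), Fam111a (9.68, others 10.20 to 10.27), Gar1 (12.42, others 12.71 to 12.76), H2ac21 (11.22, others 11.78 to 11.87), Spry4 (9.46, others 9.70 to 9.73), Umps (9.17, others 9.69 to 9.71) and Ung (10.66, others 11.48 to 11.52). It was highest there for Rragd (8.84, others 7.81 to 7.97). FK866 replicate 4 was highest for Pdk1 (9.42, others 7.40 to 7.51) and Shmt2 (9.65, others 9.14 to 9.20), and lowest for Cox6b1 (14.57, others 14.65 to 14.67) and Neu1 (11.13, others 11.43 to 11.46). FK866 replicate 3 was highest for Id2 (11.47, others 11.22 to 11.26), Ndufa1 (14.02, others 13.83 to 13.85) and Nkx2-2 (9.32, others 8.97 to 9.01), and lowest for Tnks (7.17, others 7.48 to 7.54). FK866 replicate 2 was highest for Dynlrb2 (6.74, others 6.19 to 6.26), and DMSO replicate 2 for Rnase1 (5.57, others 5.20 to 5.24), below detection in all DMSO samples.

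Culture 4 stood apart most in the genes of the hypoxia response, whose median lay above that of cultures 1 and 2 by 1.24 on the log2 scale in DMSO and by 1.55 in FK866. The shares of probes detected on the arrays of culture 4, 45.1% and 45.0%, lay within the range of the other 6 arrays (44.0% to 46.2%). They showed no sign of poorer arrays, though this share alone cannot exclude them. A difference between the litters as the whole cause is argued against by culture 3 of the same litter, which lay above cultures 1 and 2 by 0.35 in DMSO and 0.04 in FK866, on average 13.9% of the difference in culture 4. A difference in how culture 4 was grown, such as its density or oxygen supply, may account for the pattern and was not tested. The design names no group that separates culture 4, so no biological explanation was tested.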

How the results depend on the processing

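The fits without culture 4 in both groups and the litter fits and splits by culture were chosen after the results were seen, and the other alternatives before. Counts of changed genes stayed within 1.5 times of 4442 except within litter 2 and with a fold of at least 1.5 required. Litter 2 gave 1088 (552 higher and 536 lower), while litter 1 with as many samples gave 3956. Samples of the same group were less alike in litter 2 (SD of their log2 difference 0.39 in DMSO and 0.37 in FK866) than in litter 1 (0.23 and 0.25). Whether this is the cause was not tested. The fold requirement gave 2250 (1120 higher and 1130 lower), as fewer genes can qualify. Leaving out single samples gave 3762 to 4700 genes, 1869 to 2361 of them higher and 1893 to 2339 lower, 15 to 17 lists and 92 to 94 named calls against 94 with all samples. Without culture 4, 4795 genes, the same 15 lists and 94 named calls were found. With the replicate block 4656 genes were called, 4289 of them also called without it in the same direction, and the replicate block kept all 15 lists. Among genes named by the rule, the replicate block changed no call other than those of Lyz1 and Cspg4. It raised the called members of 4 lists by over 1.5 times, as given with them. Among genes named after their values were seen, it also called Lyz2 (0.00051), 7 litter genes outside the marker list, and the hypoxia genes Ankrd37, Bnip3l, Car12, Ndrg1, P4ha2 and Vegfa. The median over all genes lay between 0.01 and 0.04 on the log2 scale under every scaling tried on the log2 intensities, and the share of higher calls between 47.3% and 52.5%. Each scaling brings the arrays to a common level, so these values follow largely from it. A shift of all genes together could not be seen.

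The estimated correlation called 0 lists. A high estimate widens the error of lists whose members vary together. For the fibroblast and meningeal markers it was -0.022, below the preset 0.01, so a wider error of that list does not explain its loss (camera adjusted p of 0.034 and 0.36). Fry, which does not compare a list with other genes, called 23, of which 14 are among the 15. The litter comparison gave 6 genes from the authors' quantile table, 5 from each of the cubic spline, average and background-subtracted tables, 2 from the Z scores, 2 without a detection filter, 6 with detection p under 0.01 on all arrays, 23 with trend and robust variance, 31 with array weights, and 1 to 10 with single samples left out. The interaction gave 0 to 1 genes with single samples left out. The cause was not tested. With the replicate block as a random effect the litter comparison gave 11 genes, and with the mean of each culture's 2 arrays 0, where only 2 cultures stand against 2.

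Of 2572 values of 100 named genes under alternatives, 2524 kept their direction and side of the threshold, 33 lost a call, 10 gained one and 5 turned. Of the losses 18 fell within litter 2 and 3 within litter 1, the former including Aldoc, Cox6b1, Cox6c, Eno2, Fbln1, Flt1, Hif1a, Igf2, Ndufa1, Prox1, Rgs5, Tnks and Zfp36, beside Map2, Nadk, Nampt and Pdk1. The uncalled Afmid passed in 4 alternatives with adjusted p between 0.030 and 0.0497. Direction turned for Nmnat2 in the Z scores (-0.037 score units), for Map2 in the Z scores (0.037) and with the mean of its probes (0.17), and for Naprt with array weights (0.00025) and without DMSO replicate 4 (0.0279, over a range from -0.23 with single samples left out). Of 446 values for the 15 called lists and the hypoxia response, 424 stayed, 19 lost a call, 1 gained one and 2 turned. Camera's direction for the hypoxia list turned upward with detection p under 0.01 on all arrays (median -0.19), and ran from -0.84 without FK866 replicate 4 to -0.10 without DMSO replicate 4, where camera's direction also turned while the median stayed below 0. The cause was not tested. Signal over background limits genes seen in 1 group alone to bounds.

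With the pairing ignored, 1 of 35 splits of the arrays gave as many as 4442 changed genes, the real one, and the highest other gave 0. Each other split puts arrays of both treatments in the same group, which widens the spread within it. The splits that part all 4 pairs number 8 (highest other 0), too few for a share under 0.05. Splits that keep the pairing therefore cannot exclude chance for the genes changed by FK866. For the litter genes the 3 splits that keep the arrays of a culture together are too few for a share under 0.05 (real value 14, highest other 0). For the lists, 6 of 35 splits, the real one included, gave at least 15, and the highest other gave 19. The 5 others each exchanged 1 array between the groups and so parted 2 of 4 pairs. They kept part of the treatment difference, so they do not measure chance alone, and chance is not excluded. The highest of the others that part all 4 pairs gave 14 and the litter split 8. The median over the other splits was 10.5 lists, so with the preset correlation many lists are also called on other splits.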

Other observations

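The tests of pathway terms, histone genes, hypoxia genes without culture 4, the lower share of neural cells and the lysosomal rise were chosen after the results were seen. Ontology terms from the array's annotation, 300 with 10 to 300 measured genes, were tested with camera, and 29 were called, 9 higher and 20 lower in FK866. None was called with an estimated correlation, with adjusted p-values of at least 0.72. Beside the groups above, genes of mRNA transport fell (18 of 33, with 1 rise, adjusted p = 0.0014), as did those of tRNA processing (20 of 39, with 5 rises, adjusted p = 0.0079), RNA splicing (49 of 125, with 14 rises, adjusted p = 0.014) and nucleosome assembly (23 of 55, with 5 rises, adjusted p = 0.019). Higher in FK866 were genes of endocytosis (26 of 63, with 6 falls, adjusted p = 0.034), proton transport (18 of 34, with 4 falls, adjusted p = 0.014) and immune response (26 of 73, with 6 falls, adjusted p = 0.032). Markers of microglia and macrophages rose as well (median 1.13), and their part in these terms was not tested.

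Histone genes did not move as a block. Of 10 measured H2A genes 9 fell and 1, H2ac8, rose, with a median of -1.83, and these counts were the same under the 7 other scalings and background settings tried. Of 26 genes of the other histone families 6 fell and 2 rose, with a median of 0.04, and 5 to 7 fell and 2 to 3 rose under these settings. These copies are nearly identical, so the value of each is uncertain. Txnip, a thioredoxin-binding regulator of glucose uptake, rose by 2.67 ± 0.24 on the log2 scale (adjusted p = 3.1e-05) and its relative Arrdc4 by 2.41 ± 0.12 (adjusted p = 2.2e-06), both in 4 of 4 cultures. Both were chosen after their values were seen.

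Without culture 4, 10 of 19 hypoxia genes fell and 3 rose. Ankrd37 was at -2.21, -2.58, -3.55 and 0.23 on the log2 scale in cultures 1 to 4, with an adjusted p of 0.082 over all samples, 0.011 with the replicate block and 7.9e-05 without culture 4. Ndrg1 was at -1.32, -1.61, -3.19 and 0.34, Adm at -1.42, -1.55, -1.45 and 1.22, and Vegfa at -0.99, -1.28, -1.34 and -0.03 in cultures 1 to 4. Over all samples their adjusted p-values were 0.36, 0.34 and 0.22, and those of Ndrg1 and Vegfa with the replicate block were 0.030 and 0.0073. Lower in all 4 were also Pdk1 (-1.57, -1.95, -2.33 and -1.59), Bnip3l (-0.54, -0.59, -0.83 and -0.72), Car12 (-0.47, -0.67, -0.56 and -1.19) and P4ha2 (-1.05, -0.66, -1.59 and -0.62). Bnip3l, Car12 and P4ha2 had adjusted p-values of 0.13, 0.061 and 0.14 without a block and 0.00077, 0.0025 and 0.0018 with the replicate block. The list without culture 4 had an adjusted p of 0.095, and an adjusted p of 0.68 with an estimated correlation. Except for Pdk1 these genes were chosen after their values were seen, and the difference between culture 4 and the others rests on 1 culture and was not tested.

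The rise of microglia and macrophage markers in FK866 had a median of 1.02, 1.35, 1.24 and 0.66 in cultures 1 to 4, over 14 markers of which 1 stands in another list, with the brightest, Lyz1, at 11.3 ± 0.92 in DMSO (SD, n = 4). A lower share of neural cells as the whole cause would raise the markers of all other cells alike, if expression within each cell type stayed the same. The changes of 16 markers of other cells, 6 of them from the ependymal and choroid plexus list, had an SD of 0.95 against a median SE of 0.17. Of these, 11 were called higher and 2, Dynlrb2 (-1.64 ± 0.24) and Flt1 (-1.10 ± 0.23), lower. Their median was 0.73 against 1.13 for the microglia and macrophage markers, with no difference found by permutation over the markers (p = 0.25). These markers did not rise alike, but changes of expression within cells could also part them, so their spread cannot decide. A lower share of neural cells therefore stays open as the whole cause or as part of it. A general rise of lysosomal genes stays open, since only 1 marker stands in the autophagy and lysosome list and leaving it out could hardly move the median (1.17, or 104% of that with all 14). A larger share of microglia also stays open, since 6 of the 8 litter genes outside the list were higher in FK866 and Ccl3 (-1.14) and Ccl4 (-0.70) were lower, none called without a block, whereas with the replicate block Ccl3 (adjusted p = 0.0018) and Ccl4 (0.035) were called lower and Ccl9, Cd52, Cd99l2, Ifi27 and Lgals3bp higher (0.0016, 0.028, 0.0064, 0.0019 and 0.032). Within the list, Cd14 (-0.48) and Spi1 (-0.20) were lower in FK866 and neither was called, while 8 of the 14 were called higher. Both were chosen after their values were seen. The labels name no sort that would remove microglia or macrophages, and a response of the microglia to FK866 was not tested.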
